A study of Homo sapiens with 6 samples.

How the data were processed

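Gene expression was measured on Human OneArray oligonucleotide arrays in Hep3B, an established human hepatocellular carcinoma cell line. Per the labels' protocols, the cells had been transduced with a lentivirus carrying CCN3 or with a mock vector, RNA was extracted with Trizol, and amplified RNA was labelled with Cy5, so each array has 1 colour. The series holds 6 arrays, of which 3 are labelled CCN3 and 3 come from vector cells. The title of the third vector array names the other 2 vector samples joined by a plus sign. It was therefore not counted as an independent sample, and the comparison used 3 arrays labelled CCN3 and 2 vector arrays, with the array titled as a sum added only as an alternative. Groups and replicate numbers were taken from the titles. Nothing in the labels says that the arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

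The deposited values are probe intensities on a linear scale, with some values below 0. The scanner software, the background correction and the normalization are not given in the sources used here. In each array every value under 5000 was a whole multiple of 1 step within 0.05 steps, with a step of 0.683 to 1.43 intensity units, so each array appears scaled by a single factor. The arrays were not quantile normalized. Median intensities were 760, 738 and 757 in the arrays labelled CCN3, 801 and 783 in the vector arrays and 775 in the array titled as a sum. In steps, the medians were 574, 514 and 665 in the arrays labelled CCN3, against 902, 844 and 1135 in the vector arrays and the array titled as a sum, so the arrays labelled CCN3 were dimmer before scaling. Values below 0 numbered 540 in CCN3 replicate 2, 25 in CCN3 replicate 3, 214 in vector replicate 1 and 0 in the others. The number of arrays limits the precision.

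Genes were named through the platform annotation. Of 28264 probes, 25893 had 1 gene symbol, 0 had several and 2371 were not listed there and are unnamed here. All 25893 gene identifiers were found in a RefSeq gene table for human assembly GRCh38.p14, and 0 symbols changed. The named probes cover 19090 genes, of which 5751 have more than 1 probe. Each of these genes was represented by the probe with the highest mean where 1 probe per gene was needed. No probe sequences were used here, so the part of a transcript that a probe reads is not known.

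Values below 0 were set to 0, and log2(value + 1) was taken. The log2 differences are on that scale, which understates differences of dim probes and spreads out values near 0. For named genes with every array of a group at or under its own lower quartile (159 to 210 over the arrays compared), a bound against that floor is given instead, except for CCN3, and no difference where both groups lay under it, except for changes of sign under an alternative. This floor was chosen after the values were seen. Arrays labelled CCN3 were compared with vector arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A total of 46 gene lists with 815 genes, 764 of them with a probe, were tested with camera at a preset inter-gene correlation of 0.01 on 1 probe per gene, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The lists included markers of fibroblasts, endothelial cells, leukocytes and erythroid cells.

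The genes named were the 12 with the largest rise and the 12 with the largest fall among probes past the threshold whose arrays labelled CCN3 all lay on the same side of both vector arrays. Where fewer passed, the names were filled from probes at unadjusted p under 0.05, and because 0 probes passed, all 24 were filled in this way. CCN3, SPP1 and up to 4 members with the smallest p of each list described were added. The groups, the tests, the lists, the naming rule and the alternatives were fixed before the data were examined, except where stated.

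The alternatives were the array titled as a sum as an additional vector array or in place of either vector array, quantile normalization, median centring, filters on dim probes, an intensity trend with a robust variance prior, 1 probe or the mean of all probes per gene, the replicate number as a block, each array left out in turn, log2(value + 50), and an adjusted p under 0.01. The intensity trend with the third vector array, and with each array left out, was added after the data were seen. P-values with the trend rest mainly on the spread shared by probes of like intensity, less on each probe's own spread. With 1 vector array left, its spread was assumed to be that of the arrays labelled CCN3.

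The procedure was tested on simulated data with the probe means of these arrays, variances drawn from the prior that limma estimated, and 200 of 28264 probes changed in each of 5 sets. For 3 arrays against 2, the test recovered 0.4% of probes changed 2-fold, 31.2% of those changed 4-fold, 73.6% of those changed 8-fold and 88.4% of those changed 16-fold. Each fold was given to 250 probes over the 5 sets, and 32 unchanged probes were called in these sets. In 5 sets without changed probes it called 0 probes. The adjusted threshold depends on how many probes change and by how much, so these shares do not carry over to the real arrays. There 0 probes passed, although ACOX2, HAL and APOA2 were 16.0-, 15.5- and 14.5-fold lower (limma adjusted p 0.112 to 0.123). In the simulation the spread did not depend on intensity. In the arrays it did, with a median residual SD of 0.43 on the log2 scale in the dimmest of 3 equal groups of probes, 0.25 in the middle group and 0.22 in the brightest.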

Results

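Transcript levels were compared between Hep3B cells that had received a lentivirus carrying CCN3 and Hep3B cells that had received a mock vector. Hep3B is a line derived from a human hepatocellular carcinoma. CCN3 encodes a secreted matricellular protein of the CCN family. The series title names osteopontin, encoded by SPP1, and the coagulation cascade as the subjects of the study. There were 3 arrays labelled CCN3 and 2 separately titled vector arrays, and a further vector array, titled as the sum of those 2, is given beside them. Over probes above the median intensity, Pearson correlations were 0.939 to 0.981 among the arrays labelled CCN3, 0.978 to 0.984 among the 3 vector arrays and 0.934 to 0.958 between the groups. Over all probes the ranges were 0.953 to 0.984, 0.980 to 0.989 and 0.957 to 0.980, in the same order.

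The delivered gene was examined first. The single CCN3 probe read intensities of 46.3, -7.17 and 5.69 in the arrays labelled CCN3, against 5.33 and 33.4 in the vector arrays and 12.97 in the array titled as a sum. Its mean lay at percentile 0.75 of all probes, so it was near background in every array. The log2 difference was -1.11 (SE 1.67, limma adjusted p = 0.865). The probe did not show a higher CCN3 level in the arrays labelled CCN3. Whether it reads the delivered part of the transcript is not known, so it does not check the labels, and directions below are those of the arrays labelled CCN3 against the vector arrays.

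SPP1, which encodes the secreted phosphoprotein osteopontin, was higher in each of the 3 arrays labelled CCN3 than in either vector array. Its intensities were 10971, 13220 and 6150 in the arrays labelled CCN3, against 1226 and 883 in the vector arrays and 1203 in the array titled as a sum. The log2 difference was 3.21 (SE 0.385), a 9.25-fold higher mean on the log scale. F3, which encodes tissue factor, the initiator of coagulation, was also higher, by 1.55 on the log2 scale (SE 0.185), with a mean intensity of 7591 ± 225 (SD, n = 3) against 2598 ± 103 (SD, n = 2). Over all 28264 probes 0 passed limma's adjusted threshold, with a lowest adjusted p of 0.112, and the adjusted p was 0.135 for both SPP1 and F3. At unadjusted p under 0.05 there were 3225 probes, 991 higher and 2234 lower, where 1413 are expected by chance. This count was 2584 without CCN3 replicate 1, 5966 without CCN3 replicate 2 and 2456 without CCN3 replicate 3. With the replicate number as a block it was 1129, below the number expected by chance. The excess was therefore absent with the block, and its size otherwise depended on single arrays. Leaving out a vector array leaves 1, whose spread is assumed, so such a fit cannot show whether the excess holds. In 8719 probes, 30.8%, all 3 arrays labelled CCN3 lay on the same side of both vector arrays. The average over all groupings of 3 against 2 arrays is 20%. Probes are not independent and the other groupings were not counted, so this share does not show an excess for the real grouping. The count of probes past the adjusted threshold depended on the variance model. With a prior variance that followed intensity, SPP1 had a limma adjusted p of 8.25e-35, within a range of 1.07e-40 to 0.998 over all its alternatives. Such a low value from 5 arrays rests mainly on the spread of other probes of like intensity, not on that of SPP1. With that prior, 2198 probes passed, 684 higher and 1514 lower. That count ranged from 385 without vector replicate 1 and 572 without vector replicate 2 to 1225 without CCN3 replicate 1, 2064 without CCN3 replicate 3 and 4372 without CCN3 replicate 2.

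**Figure D1:**
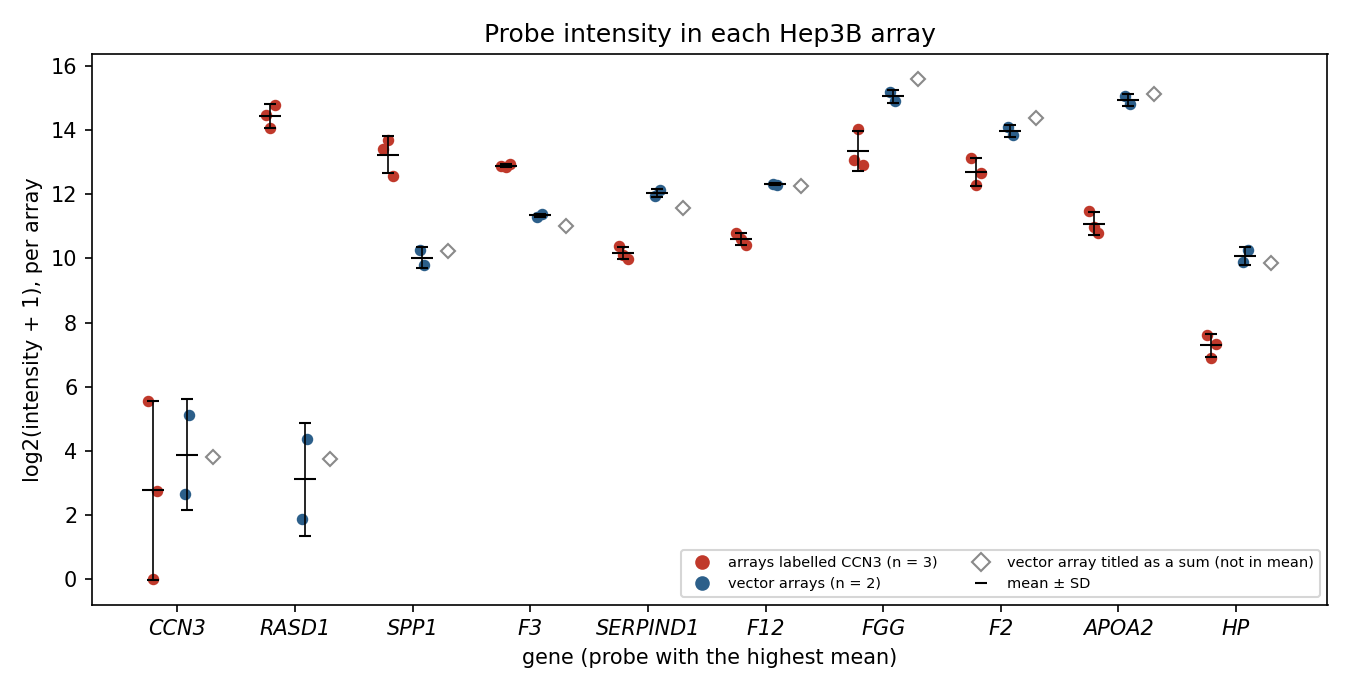
Probe intensity of 10 genes in each array, as log2(intensity + 1). Red points are the 3 arrays labelled CCN3, blue points the 2 vector arrays and grey diamonds the array titled as a sum, with bars at the mean ± SD of each group. CCN3 is near background in all arrays, SPP1 and F3 are higher in the arrays labelled CCN3 (log2 differences of 3.21 and 1.55), and FGG, F2, F12 and SERPIND1 are lower.

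The largest difference was at RASD1, which encodes a Ras-related small GTPase. Its single probe read 22782, 17052 and 28298 in the arrays labelled CCN3, against 2.66 and 19.5 in the vector arrays and 12.3 in the array titled as a sum. Against the lower quartile of each array (187 and 199 in the vector arrays), a floor chosen after the values were seen, RASD1 was at least 115-fold higher (limma adjusted p = 0.112). The other 11 genes named as highest, filled from unadjusted p under 0.05, included DIO3, the deiodinase that inactivates thyroid hormone (log2 difference 2.84, SE 0.236). UBD, a ubiquitin-like modifier, was higher by 2.63 (SE 0.240), and LTB, a membrane-bound cytokine of the tumour necrosis factor family, by 2.25 (SE 0.295). FSTL1, a secreted glycoprotein, was higher by 2.23 (SE 0.198), CALB1, a calcium-binding protein, by 2.00 (SE 0.403), and RIT1, another Ras-related GTPase, by 2.00 (SE 0.415). The rest were SPP1, given above, ZNF254 (2.07) and 3 genes whose vector arrays lay under the floor. Against it, ANKRD36BP1, a pseudogene whose probe could also read related transcripts, was at least 4.91-fold higher, OPRK1, an opioid receptor, at least 3.23-fold and TSPYL5 at least 1.57-fold. OPRK1 and ZNF254 each have a second probe, under the floor in all arrays compared. Of these 12 genes, 0 passed over all probes (adjusted p 0.112 to 0.240), and 12 passed with the intensity trend.

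The 12 genes named as lowest were also filled from unadjusted p under 0.05. ACOX2, a peroxisomal oxidase of bile acid synthesis, had a log2 difference of -4.00 (SE 0.341), with mean intensities of 969 ± 97.1 (SD, n = 3) and 16465 ± 7877 (SD, n = 2). HAL, histidine ammonia-lyase, was lower in both of its probes (-3.95, SE 0.316, and -3.39, SE 0.354). APOA2, an apolipoprotein of high-density lipoprotein, was at -3.86 (SE 0.275) and AHSG, which encodes fetuin-A, at -3.04 (SE 0.384). GPAT3, an acyltransferase of glycerolipid synthesis, was at -2.92 (SE 0.202), and the keratin KRT23 at -3.45 (SE 0.252). DIXDC1 was at -2.64 and, in a second probe, at -1.35 (SE 0.260). PDGFRB was at -2.58 and PCDH15 at -2.52. PCDH15 had 3 dimmer probes, of which 1 gave 0.11 and the others lay under the floor in all arrays compared. In the other 3 genes the arrays labelled CCN3 lay under the floor. Against it, HP, which encodes haptoglobin, was at least 5.88-fold lower, S100A9 at least 2.39-fold and NPFF at least 1.26-fold, so the rank of NPFF, first by log2 difference, rests on values near background. Of these 12 genes, 0 passed over all probes (limma adjusted p 0.112 to 0.372), and 12 passed with the intensity trend.

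Coagulation genes, which the series title names, were lower as a group in the arrays labelled CCN3, with F3 in the opposite direction. The median log2 difference of 27 measured coagulation genes was -0.36 (camera adjusted p = 0.00882, preset correlation). It was not past the threshold with an estimated correlation (adjusted p = 0.946 with an estimated correlation). The thrombin inhibitor SERPIND1 was at -1.88 (SE 0.219), F12 at -1.71 (SE 0.209), the fibrinogen chain FGG at -1.72 (SE 0.391) and prothrombin, F2, named after its value was seen, at -1.28 (SE 0.306). Over all probes 0 members passed, and adjusted over the list alone 4 fell (SERPIND1, F12, FGG and F2) and 1, F3, rose. The list median was -0.22 without CCN3 replicate 2 (adjusted p = 0.0150), -0.25 with dim values raised to the floor, -0.55 with all 3 vector arrays, -0.57 and -0.59 with the array titled as a sum in place of vector replicates 1 and 2, and -0.62 without the dimmest 50% of probes. In 14 members every array labelled CCN3 lay below both vector arrays, and in 1 above. The fibrinolysis list did not pass (11 genes, adjusted p = 0.630, median 0.01, with a negative camera direction). Over all probes 0 passed, and adjusted over the list alone 2 fell, the carboxypeptidase CPB2 (-1.58, SE 0.301) and the protease inhibitor A2M (-1.08, SE 0.221, but -0.60 with the mean of its probes). Its other named members were S100A10 (0.64) and SERPINF2 (-0.88). Of the 3 thrombin receptors measured (list adjusted p = 0.522), F2R was at -0.40, and F2RL2 and F2RL3 lay under the floor in both groups, with 0 past over all probes and 0 adjusted over the list alone.

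Secreted proteins of hepatocytes were lower as a group (30 genes, median -0.44, camera adjusted p = 2.57e-06, and adjusted p = 0.946 with an estimated correlation). Over all probes 0 members passed, and adjusted over the list alone 11 fell and 0 rose, among them APOA2, HP, APOM (-2.08, SE 0.239) and AHSG. The acute phase list was lower too (16 genes, median -0.65, adjusted p = 0.00226, and adjusted p = 0.946 with an estimated correlation), with 0 members past over all probes and 6 lower adjusted over the list alone. These included HP, the orosomucoids ORM1 (-1.73, SE 0.291) and ORM2 (-1.68, SE 0.321), and FGG. Hepatocyte transcription factors had a median of -0.55 (11 genes, adjusted p = 0.0146, and adjusted p = 0.946 with an estimated correlation), with 0 past over all probes and 1, CEBPA (-1.04, SE 0.186), lower adjusted over the list alone. PPARA (-0.69), FOXA3 (-0.57) and PROX1 (-1.12, and -0.66 with the mean of its probes) did not pass. Without vector replicate 1 this list had an adjusted p of 0.0508. Complement genes had a median of -0.41 (26 genes, adjusted p = 0.0251, and adjusted p = 0.958 with an estimated correlation), with 0 past over all probes and 0 adjusted over the list alone, and CFI, SERPING1 and MASP1 at -0.77, -0.78 and -0.87, but MASP1 at -0.15 with the mean of its 3 probes. MBL2 was at least 1.65-fold lower against the floor. The complement call was lost without CCN3 replicate 2 (adjusted p = 0.144), without vector replicate 1 (adjusted p = 0.0533), with the array titled as a sum in its place (0.0686) and without the dimmest 50% of probes (0.190), and the median was -0.27 without CCN3 replicate 2 and -0.16 without vector replicate 2.

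Immediate early genes and feedback inhibitors of ERK signalling had a median of -0.83 (20 genes, camera adjusted p = 5.46e-06, and adjusted p = 0.946 with an estimated correlation). Over all probes 0 passed, and adjusted over the list alone 9 fell and 0 rose, including the transcription factor ETV5 (-1.38, SE 0.242), the ERK pathway inhibitors SPRY2 (-1.48, SE 0.261) and SPRED1 (at least 1.23-fold lower against the floor), and FOSB (-1.63, SE 0.299). The list median was -0.60 with dim values raised to the floor and -0.27 without the dimmest 50% of probes. Genes of the integrated stress response had a median of -0.57 (20 genes, adjusted p = 2.92e-05, and adjusted p = 0.946 with an estimated correlation). In that list 0 passed over all probes and 4 fell adjusted over the list alone. These were the amino acid enzymes CTH (-2.07, SE 0.335), PHGDH (-1.91, SE 0.338) and ASNS (-1.43, SE 0.267), and the lipoprotein receptor VLDLR (-2.26, SE 0.590). The unfolded protein response list had a median of -0.55 (20 genes, adjusted p = 3.55e-04, and adjusted p = 0.946 with an estimated correlation), with 0 past over all probes and 1, CREB3L2 (-1.26, SE 0.206, but -0.54 with the mean of its 3 probes), lower adjusted over the list alone. EDEM1, DNAJC3 and MANF were at -0.92, -1.09 and -0.70, and DNAJC3 at -0.66 with the mean of its probes.

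**Figure D2:**
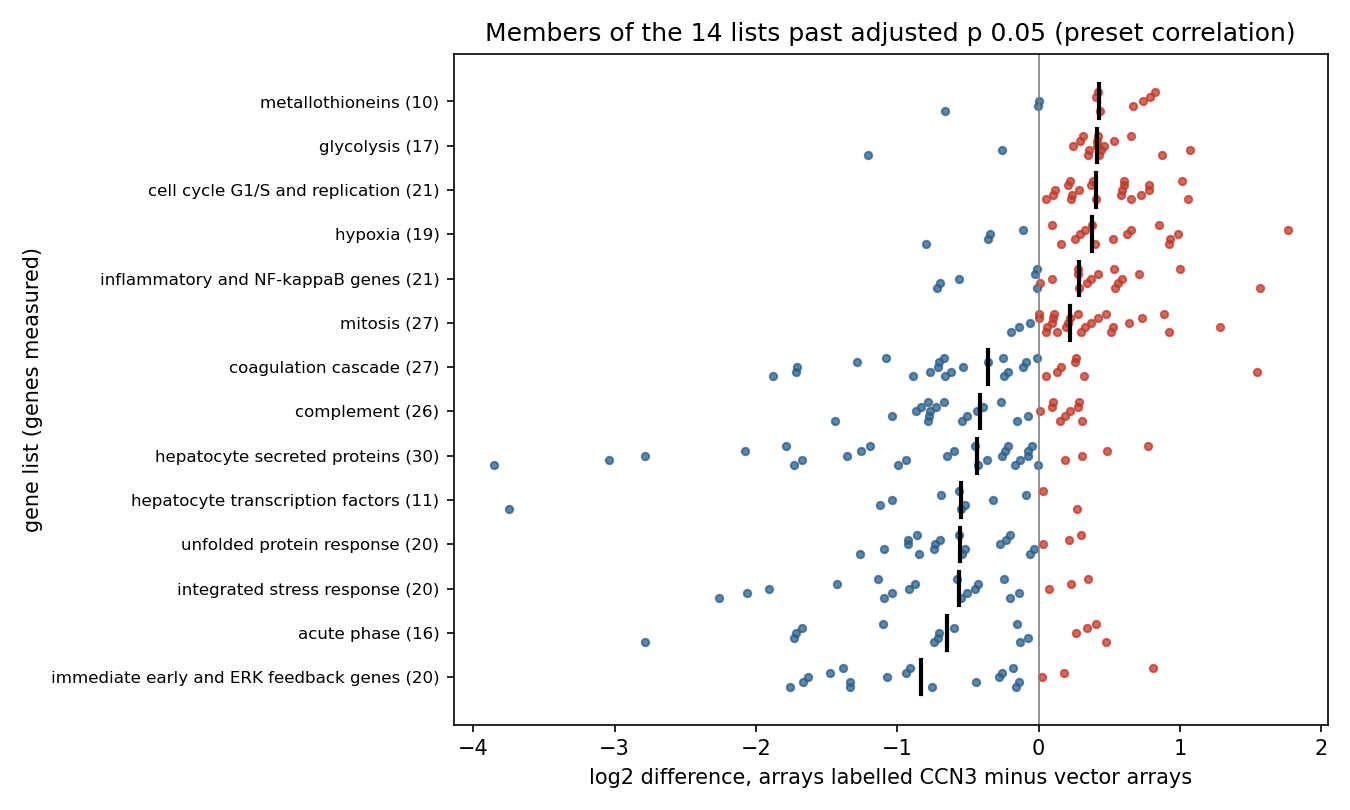
Log2 differences, arrays labelled CCN3 minus vector arrays, of each measured member of the 14 gene lists past adjusted p 0.05 with the preset correlation; 0 of these lists passed with an estimated correlation. Each point is a gene (red above 0, blue at or below 0), and black bars are list medians, from -0.83 for the immediate early and ERK feedback genes to 0.43 for the metallothioneins.

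Genes of the G1/S transition and DNA replication were higher as a group (21 genes, median 0.41, camera adjusted p = 9.90e-07, and adjusted p = 0.946 with an estimated correlation). The members with the smallest p were CCNE1 (1.06, SE 0.261), MCM4 (1.02, SE 0.267), PCNA (0.78, SE 0.254) and SLBP (0.73, SE 0.201), and 0 members passed over all probes or adjusted over the list alone. Mitosis genes had a median of 0.23 (27 genes, adjusted p = 0.00882, and adjusted p = 0.946 with an estimated correlation), with BIRC5 at 0.92, AURKA at 0.42, CCNA2 at 0.51 (0.04 with the mean of its probes) and PLK1 at 0.64, and 0 past over all probes or adjusted over the list alone. The median was 0.11 without CCN3 replicate 2 (adjusted p = 0.725) and 0.34 without CCN3 replicate 3, and the call was lost with the array titled as a sum in place of vector replicate 1 or 2 (adjusted p = 0.0654 and 0.109). In CCN3 replicate 2, 763 of 10643 genes above the median intensity were over 2-fold above the mean of the other arrays labelled CCN3, against 28 and 68 in CCN3 replicates 1 and 3. Glycolysis genes had a median of 0.41 (17 genes, adjusted p = 8.19e-04, and adjusted p = 0.946 with an estimated correlation), with HK2 at 1.07, PFKP at 0.87 and ALDOA at 0.43, whereas PFKM was at -1.21. Hypoxia-responsive genes had a median of 0.38 (19 genes, adjusted p = 0.00128, and adjusted p = 0.946 with an estimated correlation), with the glucose transporter SLC2A3 at 1.76 (SE 0.414, and 1.05 with the mean of its probes), PFKFB3 at 0.92, ADM at 0.86 and PFKFB4 at 0.98. The hypoxia median was 0.13 without CCN3 replicate 1 (adjusted p = 0.0395), 0.66 without CCN3 replicate 3 and 0.59 without vector replicate 1. In both lists 0 members passed over all probes and 0 adjusted over the list alone.

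Inflammatory and NF-kappaB genes had a median of 0.29 (21 genes, camera adjusted p = 0.00362, and adjusted p = 0.946 with an estimated correlation). Over all probes 0 passed, and adjusted over the list alone 2 rose, the cytokine IL32 (1.57, SE 0.226) and the chemokine CXCL1 (1.00, SE 0.191). CXCL3 was at 0.54 and RELB at 0.59. Metallothioneins, which bind zinc and copper, had a median of 0.43 (10 genes, adjusted p = 0.00898, and adjusted p = 0.946 with an estimated correlation). MT2A was at 0.79, MT3 at 0.74 and MT1F at 0.67, whereas MT1E was at -0.66, and 0 passed over all probes or adjusted over the list alone. Without vector replicate 2 neither list passed (adjusted p = 0.0590 and 0.0772), nor the inflammatory list with the array titled as a sum in its place (adjusted p = 0.0552).

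The other 32 lists did not pass (camera adjusted p 0.0790 to 0.939). In the CCN family list (6 genes, adjusted p = 0.630, median -0.03 with a positive camera direction), CCN2 was at -0.73 and CCN1 at 0.73, and CCN5 was at least 1.23-fold higher against the floor. The list of osteopontin receptors and related bone phosphoproteins (15 genes, adjusted p = 0.630, median -0.06 with a positive camera direction) held SPP1, which alone rose adjusted over the list alone, beside ITGA5 at -0.83 and ITGB5 at -0.39, with MEPE under the floor in both groups. In both lists 0 members passed over all probes. The 4 lists of markers of other cell types did not pass. Their medians were -0.04 for fibroblasts (adjusted p = 0.790), -0.02 for endothelial cells (adjusted p = 0.939), -0.13 for leukocytes (adjusted p = 0.415) and 0.10 for erythroid cells (adjusted p = 0.676, with a negative camera direction). Over all probes 0 of these markers passed, and adjusted over the list alone 1 fell, PDGFRB. The markers with the smallest p in the other lists were FLT1 (-1.81, and -0.64 with the mean of its probes) for endothelial cells, CD14 (-0.93) for leukocytes and HBA1 (-0.87) for erythroid cells.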

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

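The intensity trend combined with the array titled as a sum, or with each array left out, was chosen after the results were seen; all other alternatives were planned. The count of probes past limma's adjusted threshold, 0 as reported (3225 at unadjusted p under 0.05), stayed at 0 under median centring and the mean of all probes of a gene; at adjusted p under 0.01 it could only be 0. It was 310 (67 higher, 243 lower; 306 at least 2-fold) with all 3 vector arrays, 1 with the array titled as a sum in place of vector replicate 1 and 2 in place of vector replicate 2, all of them at least 2-fold. Quantile normalization gave 157, all at least 2-fold. With only probes above the lower tercile of intensity the count was 504 (479 at least 2-fold), and without the dimmest 50% of probes it was 438 (385). The intensity trend with a robust prior gave 2198 (925), 1 probe per gene 4 (4), and log2(value + 50) 473 (471). All 473 of the latter were among the 2198. With all 3 vector arrays and the trend there were 2664 (846). Leaving out each array gave 0 to 3 probes, or 385 to 4372 with the trend, and 0 to 1147 at least 2-fold over both. The count at unadjusted p under 0.05 was 5283 after quantile normalization, 5013 with the intensity trend and 1024 to 5966 when each array was left out without the trend. The filters test fewer probes and remove those with the widest spread; the cause of the other shifts was not tested. Dim probes had the widest spread (median residual SD 0.43 in the lowest tercile, 0.22 in the highest), so low signal over background limits calls among them.

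SPP1 stayed higher in every alternative, but leaving out an array could not reverse it, since every array labelled CCN3 exceeded both vector arrays. It passed at 3.14 with all 3 vector arrays, with and without the trend, at 3.27 after quantile normalization, at 3.21 with either filter and with the trend, and at 3.15 with log2(value + 50). Leaving out each array gave 2.97 to 3.53, past the threshold only with the trend. CCN3 ranged from -2.51 to 0.27 when each array was left out, turning positive without CCN3 replicate 2 and, at 0.11, without vector replicate 2.

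Of the 14 gene lists past the threshold, 0 passed with an estimated correlation or with fry, and 12 to 15 passed elsewhere. The coagulation median, -0.36, had an adjusted p of 0.946 with an estimated correlation and 0.321 with fry, and at most 0.0333 in the other alternatives. With the array titled as a sum in place of a vector array, the mitosis list lost its call (adjusted p = 0.0654 and 0.109), as did complement for vector replicate 1 (0.0686) and the inflammatory list for vector replicate 2 (0.0552). Without the dimmest 50% of probes complement lost its call (0.190), and the medians were -0.27 for immediate early genes, -0.62 for coagulation (also above the lower tercile) and 0.74 for metallothioneins. The coagulation median was -0.55 with all 3 vector arrays and -0.57 and -0.59 with each vector array replaced, the mitosis median 0.15 with all 3 and 0.34 with the replicate block, the hypoxia median 0.66 with the block, and the complement median -0.26 with vector replicate 2 replaced and -0.15 for the mean of all probes. With values under the lower quartile of each array raised to it, a step added after the results were seen, the medians of coagulation, complement and immediate early genes were -0.25, -0.33 and -0.60. All 14 lists kept the sign of their medians. Those of 8 lists that did not pass changed sign. Fibrinolysis (0.01) was at -0.15 with all 3 vector arrays, with and without the trend, at -0.18 and -0.21 with vector replicates 1 and 2 replaced, at -0.15 for the mean of all probes and at -0.21 with the replicate block. The endothelial list (-0.02) was at 0.10 with all 3 vector arrays, with and without the trend, at 0.19 and 0.18 with each vector array replaced, at 0.045 after quantile normalization, at 0.057 after median centring, and at 0.037 and 0.25 with the filters. The CCN family (-0.03) was at 0.059 with vector replicate 2 replaced, at 0.00054 after quantile normalization, at 0.043 after median centring, at 0.33 above the lower tercile and at 0.11 with log2(value + 50). The osteopontin receptor list (-0.06) was at 0.018 after quantile normalization and after median centring, at 0.0017 above the lower tercile and at 0.014 with log2(value + 50). The fibroblast list (-0.04) was at 0.15 after quantile normalization, at 0.036 after median centring and at 0.042 with log2(value + 50). The erythroid list (0.10) was at -0.042 with vector replicate 2 replaced, at -0.50 with either filter and at -0.026 with the replicate block. The mesenchymal list (0.02) was at -0.30 without the dimmest 50% and at -0.078 with the replicate block, and the interferon list (-0.09) was at 0.025 after quantile normalization. Leaving out each array gave -0.21 to 0.18 for fibrinolysis, -0.15 to 0.18 for the endothelial list, -0.22 to 0.37 for the CCN family, -0.24 to 0.30 for the osteopontin receptor list, -0.19 to 0.26 for the fibroblast list, -0.12 to 0.32 for the erythroid list, -0.078 to 0.072 for the mesenchymal list and -0.29 to 0.083 for the interferon list. The cause was not tested.

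Of 115 other genes named by the rule, 111 kept their direction in every alternative that gave a value. The filters removed the probes of CCN3 and of 14 of these genes below the lower tercile and 31 below the median, including all 3 measured protease-activated receptors, so these genes and that list have no value there. The others were LUM and HBB, at -1.82 and 0.13 with the mean of all probes, since a second probe near background entered the mean, and F2RL2 and F2RL3, at -1.12 to 0.28 and -0.56 to 0.086 when each array was left out. LUM, F2RL2 and F2RL3 lay near background in both groups, so their signs carry no information. The mean of all probes moved 17 named genes by over 1.5 times, among them CCNA2 to 0.04, MASP1 to -0.15, CREB3L2 to -0.54, A2M to -0.60, FLT1 to -0.64, DNAJC3 and PROX1 to -0.66, PCDH15 to -0.91, SLC2A3 and OPRK1 to 1.05 and ZNF254 to 1.13. The replicate numbers 1 and 2 occur in both groups, but groups of 3 and 2 share only those numbers. Over all probes the deviations of same-numbered arrays from their group means correlated at -0.607 and -0.524. Over probes above the median they correlated at -0.03 and -0.17. The numbers were therefore not taken to pair the arrays. With 2 vector arrays the deviations mirror each other. Over all probes CCN3 replicate 1 thus correlated at 0.607 with vector replicate 2, and CCN3 replicate 2 at 0.524 with vector replicate 1. This pattern ran across the groups, the main fit does not model it, and its cause was not tested. With the replicate block 0 probes passed, and 1129 had an unadjusted p under 0.05, fewer than the 1413 expected by chance.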

Other observations

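The list tests and the fit with all 3 vector arrays were planned; the tests of explanations and the splits in this part were chosen after the results were seen, except those of gene span, of array scaling and of CCN3 replicate 2 alone. Epithelial markers moved in both directions in the arrays labelled CCN3 (16 genes, median -0.28, camera adjusted p = 0.522). Adjusted over the list alone KRT8 (-1.26, SE 0.222) fell and EPCAM (1.04, SE 0.216) rose, with 0 past over all probes, beside the claudin CLDN4 at 1.07 (SE 0.303) and E-cadherin, CDH1, at -1.49 (SE 0.425). Mesenchymal markers had a median of 0.02 (14 genes, adjusted p = 0.939, with a negative camera direction), with SNAI1 at -0.61, VIM at 0.58, FN1 at -0.40 (-0.20 with the mean of its probes) and S100A4 at 0.42. The interferon list had a median of -0.09 (27 genes, adjusted p = 0.630), with IFI35, IFIT1, HERC5 and OASL at -0.79, -0.77, -0.92 and -0.72. In the mesenchymal and interferon lists 0 genes passed over all probes and 0 adjusted over the list alone.

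Genes with several probes were picked out after their values were seen. All 4 probes of IL32 were higher in the arrays labelled CCN3, with log2 differences of 1.26 (SE 0.200), 1.28 (SE 0.241), 1.50 (SE 0.229) and 1.57 (SE 0.226). ADH6, an alcohol dehydrogenase, was lower in both probes, at -1.77 (SE 0.215) and -2.43 (SE 0.229). The limma adjusted p of these probes was 0.123 to 0.224.

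With all 3 vector arrays, 310 probes passed in the real grouping of the 6 arrays and at most 13 in any other split into 3 and 3, so 1 of 10 splits gave as many. The splits are too few for a share under 0.05. Whether the array titled as a sum was a mixture of RNA or a separate sample stayed unknown. Its values were within 1 step of the mean of both vector arrays at 411 probes. Over 14132 probes, the spread of its distance from that mean had a variance ratio of 1.34 to that between the vector arrays. Independent arrays of equal spread give 0.75.

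RASD1 was bright in the arrays labelled CCN3 and near background in the vector arrays, whereas the CCN3 probe was near background in all. A defect of spots on single arrays is argued against, because the 3 arrays labelled CCN3 read RASD1 within a log2 range of 0.73 and the array titled as a sum, not used in choosing the gene, read 12.3. Single arrays under the wrong group name stay open. Over probes above the median 0 arrays correlated better, on average, with the other group than with their own, but over all probes 2 did, CCN3 replicates 1 (0.972 against 0.968) and 2 (0.961 against 0.958). A CCN3 probe that does not read the delivered transcript may explain its low signal, but its percentile of 0.75 cannot show this, and it cannot be told apart here from a low CCN3 level. Whether RASD1 responds to CCN3, or to the site or content of the vector, was not tested.

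CCN3 replicate 2 stood apart from the other arrays labelled CCN3. Transcripts including CENPF (12072 against 1352 and 1174), KIF11 (10756 against 2840 and 1977) and APOB (17400 against 3428 and 2253) were brighter in it, genes chosen after their values were seen. Its deviation from the other 2 followed the genomic span of the gene (Spearman rho 0.20 across 10643 genes, which are not independent replicates), against -0.03 and -0.25 for CCN3 replicates 1 and 3, whose deviations are measured partly against it. More cells in mitosis would raise longer and shorter genes of the mitosis list alike. The 12 longer ones deviated by 1.64 more than the 12 shorter ones (permutation p = 0.00446, 100000 resamples, two-sided). The longer ones include CENPF and KIF11, chosen above for their brightness, and the permutation took genes of 1 array as independent. The difference therefore argues only weakly against more cells in mitosis as the whole explanation. A difference in RNA or amplification, or a biological difference of that sample, may set CCN3 replicate 2 apart. Neither was tested, and the genomic span of a gene is not the length of its transcript, which was not examined.

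Secreted proteins of hepatocytes had a median of -0.44 in the arrays labelled CCN3 against the vector arrays (camera adjusted p = 2.57e-06 with the preset correlation, but 0.946 with an estimated correlation and 0.145 with fry). Array scaling as the whole cause is argued against by the list median after quantile normalization, -0.39 (bootstrap 95% interval -1.05 to -0.15). CCN3 replicate 2 alone is argued against by the median without it, -0.41 (-1.19 to -0.12). Both intervals describe the spread over the genes of the list, not the spread between arrays. Hep3B is a cell line, so a culture of it should hold no other cell type to replace the hepatoma cells. Fewer hepatoma cells would lower all members alike only if their probes responded alike. The 30 members lay at a mean squared distance of 15.2 squared standard errors from a common fall, where equal falls gave a median of 1.38. As large a value came in 2 of 10000 simulations that took the members as independent. The 25 members without the 5 brightest lay at 15.8, which 0 of 10000 simulations reached. The members therefore did not fall alike. Unequal probe response or background could also give this, so the distances alone decide nothing about the share of hepatoma cells. The marker lists of fibroblasts, endothelial cells, leukocytes and erythroid cells did not pass, with medians of -0.04, -0.02, -0.13 and 0.10. Neither the design nor these lists gave a sign of other cells. A partial loss of hepatocyte gene expression in these cells stays a hypothesis. Separate cultures in which CCN3 itself is measured could test it; here the CCN3 probe did not show the delivered gene.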
